A study of Arabidopsis thaliana with 5 samples.

How the data were processed

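The data are whole-genome bisulfite calls of leaf DNA from 5 libraries, 1 each of Col-0 mock, Col-0 Pst, METS1#1 mock, METS1#1 Pst and METS1#2 Pst, with groups taken from the sample titles. Libraries were made from sheared DNA, treated with bisulfite, amplified and sequenced by a service provider, per the labels' protocols. Reads were aligned with Bismark to TAIR10, per the submitters' processing notes; version, trimming and removal of duplicates are not given in the sources used here. The deposited tables give, for each cytosine and strand, the count of methylated calls and the count of all calls, with the genes whose promoter or gene holds the cytosine. These counts were used as deposited. No cytosine has fewer than 5 calls, so the authors' tables leave out cytosines of low coverage, and a low-coverage library lists fewer cytosines. Listed nuclear CG cytosines numbered 1730845, 1629968, 1638250, 1206380 and 729712 in the order above, with median coverage of 7, 7, 9, 7 and 6.

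The methylation level of a library was the methylated calls over all calls at nuclear cytosines with at least 5 calls in all 5 libraries (414587 CG, 436022 CHG and 1170343 CHH cytosines), with a 95% Wilson interval. Unconverted cytosines were gauged on the plastid genome, where the CHH level was 0.903%, 0.917%, 0.986%, 0.877% and 0.863% (exact 95% intervals within 0.856 to 0.992). The 5 comparisons were METS1#1 mock against Col-0 mock, METS1#1 Pst and METS1#2 Pst each against Col-0 Pst, and Pst against mock in Col-0 and in METS1#1. With 1 library per group no test between conditions was made, and intervals cover counting error only. Intervals and tests treat calls as independent, although a read can give calls at several cytosines. Intervals may thus be too narrow and p-values too small.

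Windows of 200 bp with at least 3 cytosines of a context, and gene promoters and bodies with at least 10, each with 5 calls in both libraries, were tested with a two-sided Fisher's exact test on summed calls. P-values were adjusted by Benjamini-Hochberg within context and comparison. A call needed an adjusted p below 0.01 and a difference of at least 40 (CG), 20 (CHG) or 10 (CHH) percentage points. Counting error was simulated by 10 binomial draws at the pooled level per comparison. The procedure was tested on simulated data: for METS1#1 mock against Col-0 mock, 86% of raised and 76% of lowered CG windows were recovered at a true difference of 60 points among 153613 windows, 41% and 25% of CHG windows at 30 points among 185147, and 32% and 27% of CHH windows at 15 points among 309044, with 0 false calls. For METS1#2 Pst against Col-0 Pst, recovery was 15% and 15% in CHH among 212134 windows and 19% and 7% in CHG among 98674. For METS1#1 Pst against Col-0 Pst it was 14% and 8% in CHH among 284182 windows. Lowered windows were found less often than raised ones in several cases. The 2 sets started from different levels, since only windows with enough methylation could be lowered. Their recoveries therefore do not compare the directions at like levels. Simulated calls were independent, so the 0 false calls cover independent counting error only.

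Promoters and gene bodies follow the annotation columns of the deposited tables. Their promoters span a median of 1931 bp and overlap the gene, and 60.3% of promoter CHH cytosines lie inside their own gene, so the planned promoter of 1 kb upstream could not be used, nor its longer alternative. Exons and introns of METS1 and transposon families were not used here, since no genome annotation was at hand. Of 31881 identifiers in the tables, 2202 are transposons and 28951 matched the RefSeq gene table of TAIR10.1, which was used for names and gene types only. Pericentromeres were set in advance, for example from 12 to 18 Mb on chromosome 1.

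Named genes follow a rule set before the data were examined: METS1; the 4 protein-coding genes with the largest rise and the 4 with the largest fall per context among called genes in each METS1 comparison; 2 and 2 in each infection comparison; called members of the 9 gene lists, at most 4 per list; and the 5 windows per direction with the largest smaller difference among those called in both lines, of which some are given. Gene lists (112 genes, all found) were fixed at the same time, and their median differences were ranked among 10000 random lists matched on mean level over the 5 libraries and covered cytosines.

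Alternatives set in advance were a minimum of 10 calls, thinning the deeper library to equal coverage at each cytosine (seed 20), cytosines covered in the compared libraries only, the mean of single cytosines, correction by the plastid level, 500-bp windows, single cytosines, 20, 10 and 5 points as thresholds, and 6 cytosines per window. Added after the data were seen were removal of cytosines over 100 reads, the mean of single cytosines for region classes, promoter cytosines outside the gene, coverage and CG level of METS1 at cytosines listed in all libraries, CHH windows with CG at 20% or more, alternatives for gene counts and the infection response, and the look at strands and CG levels of CHH calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.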

Results

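Bisulfite sequencing calls were examined for leaf DNA of 5 groups of 4-week-old Arabidopsis thaliana plants, with 1 library per group. METS1 (AT5G17920) encodes a cytosolic methionine synthase, an enzyme of the cycle that supplies the methyl donor S-adenosylmethionine to DNA methyltransferases. Wild-type Col-0 and the overexpressing line 35S::METS1#1 (METS1#1) were each infiltrated with 10 mM MgSO4 (mock) or inoculated with the bacterial pathogen Pseudomonas syringae (Pst), and a separate overexpressing line, 35S::METS1#2 (METS1#2), was inoculated only. The design asks whether METS1 overexpression goes with another level of cytosine methylation in the CG, CHG and CHH contexts (H is A, C or T), with and without the bacterium. The labels name 3 biological replicates of 4 plants per condition but give 1 library for each, so no difference below has a replicate check, and every test compares 2 libraries, not conditions. METS1#1 Pst and METS1#2 Pst came from 2 sequencing runs and the other 3 libraries from 1 run, so sequencing runs and the combination of METS1 with Pst cannot be told apart. Depth was unequal: nuclear CHH calls numbered 59883395 in Col-0 mock, 53930054 in Col-0 Pst, 59198859 in METS1#1 mock, 36916291 in METS1#1 Pst and 21157558 in METS1#2 Pst.

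The METS1 gene itself (chromosome 5, positions 5935037 to 5939288 from its first to its last listed CG cytosine, TAIR10) carried more reads in all 3 METS1 libraries. Coverage of its gene body, relative to the median gene of the same library, was 2.12 times that of Col-0 mock in METS1#1 mock, 2.98 times that of Col-0 Pst in METS1#1 Pst and 3.95 times that of Col-0 Pst in METS1#2 Pst. Among 24100 genes ranked by the same ratio, METS1 had 210, 8 and 4 genes above it, respectively. A cytosine with fewer than 5 calls is unlisted and counts as 0 here, and the median gene had 5.93 calls per cytosine in METS1#1 mock, 3.46 in METS1#1 Pst and 1.84 in METS1#2 Pst, so the sizes of the 3 ratios also follow depth. Over the 470 cytosines of the body listed in all 5 libraries the ratios were 1.66, 1.95 and 1.91, with 18, 0 and 1 of 4194 genes above METS1. Its annotated promoter region, which overlaps the gene, had 2.09, 2.32 and 1.85 times the coverage of Col-0 given the same treatment. The part outside the gene held 21 cytosines listed in any library, of which 13 were listed in Col-0 mock, 18 in Col-0 Pst, 9 in METS1#1 mock, 18 in METS1#1 Pst and 1 in METS1#2 Pst, too few and too unlike for a comparison of coverage. The CG level of the METS1 body was 14.9% in Col-0 mock (95% Wilson interval 12.8 to 17.2), 18.04% in Col-0 Pst (15.4 to 21.0), 11.9% in METS1#1 mock (10.6 to 13.3), 12.3% in METS1#1 Pst (10.6 to 14.2) and 11.6% in METS1#2 Pst (9.79 to 13.8). These levels rest on 114, 89, 127, 119 and 103 listed CG cytosines of 148. At the 61 listed in all 5 libraries they were 18.2%, 21.5%, 13.3%, 13.8% and 11.8%, in the same order. Reads of the plant's own METS1 gene and of a METS1 copy introduced for overexpression were not told apart. Coverage and CG levels in the METS1 libraries may therefore mix the gene and the copy. Whether the plant's own gene was less methylated in these lines was not tested. CHG and CHH levels of the body stayed between 0.754% and 1.45% in the 5 libraries.

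**Figure D1:**
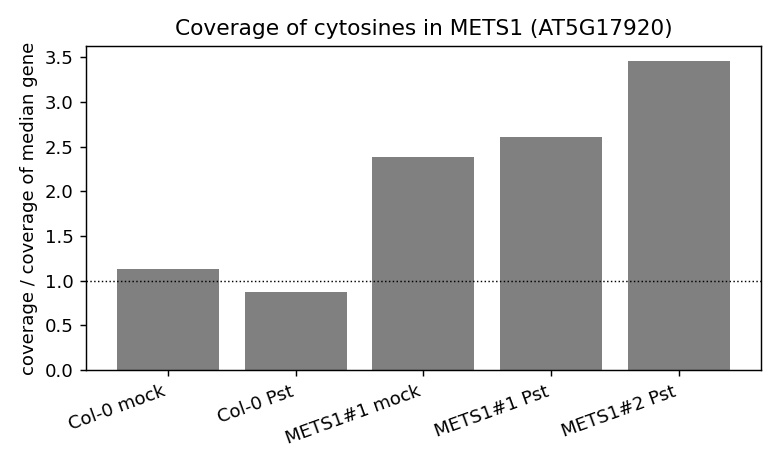
Coverage of cytosines in the METS1 gene body divided by the coverage of the median gene of the same library (vertical axis, ratio; unlisted cytosines count as 0), for each of the 5 libraries; the dotted line marks a ratio of 1. The bars stand at 1.13 and 0.874 in the Col-0 libraries and at 2.39, 2.60 and 3.45 in the METS1 libraries.

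Transposons were more methylated in each METS1 library than in the Col-0 library given the same treatment, in all 3 contexts. The CHH level in transposons was 11.7% in METS1#1 mock against 10.7% in Col-0 mock, a difference of 1.04 percentage points. After inoculation it was 10.8% in METS1#1 and 10.6% in METS1#2 against 9.78% in Col-0, differences of 0.978 and 0.809 points. CG levels in transposons were 76.0% and 74.6% in METS1#1 mock and Col-0 mock, and 72.3%, 72.0% and 70.6% in METS1#1 Pst, METS1#2 Pst and Col-0 Pst. CHG levels were higher by 1.38 points in METS1#1 mock, 1.40 points in METS1#1 Pst and 1.02 points in METS1#2 Pst. The inoculated library was below the mock library in both genotypes, by a CG difference of -4.04 points in Col-0 and -3.64 points in METS1#1 and by CHH differences of -0.890 and -0.949 points. These signs were the same when single cytosines were averaged, although the CG difference of METS1#1 mock shrank from 1.34 to 0.441 points. The 2 Col-0 libraries thus differed in transposon CHH by about as much as METS1 libraries differed from Col-0, and no replicate library shows how far like samples vary.

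**Figure D2:**
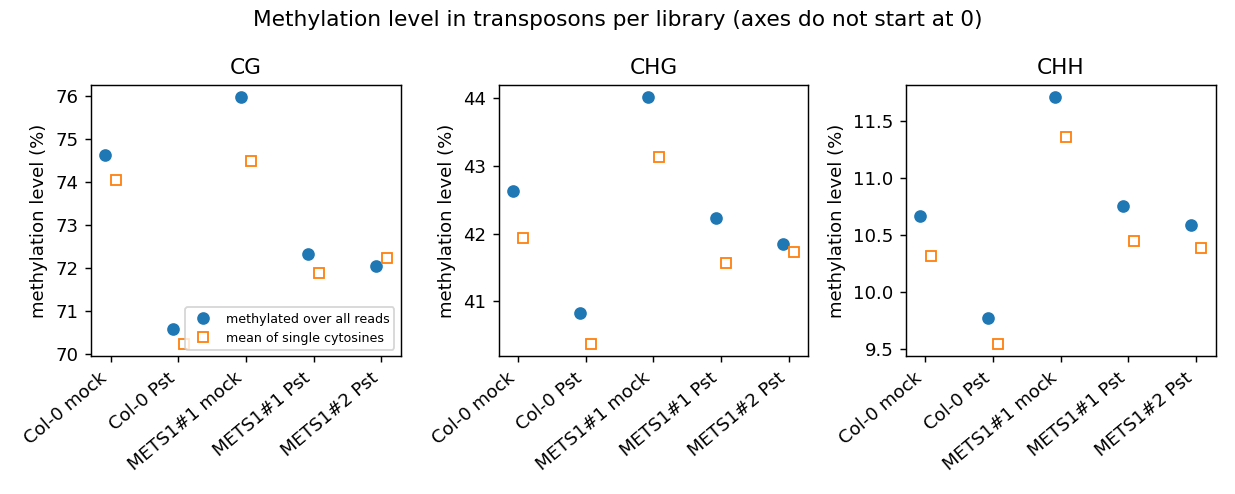
Methylation level (vertical axis, percent) of nuclear cytosines inside annotated transposons for the 5 libraries, in CG, CHG and CHH; filled circles are methylated over all reads and open squares the mean of single cytosines, and the axes do not start at 0. CHH reaches 11.7% in METS1#1 mock and 10.7% in Col-0 mock by reads, and the inoculated libraries lie below the mock libraries of their genotype.

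Over all nuclear cytosines with at least 5 calls in all 5 libraries, the direction of the METS1 difference depended on how cytosines were averaged. Counted over reads, the CG level was 18.2% in Col-0 mock (95% Wilson interval 18.2 to 18.3) and 15.9% in METS1#1 mock (15.9 to 15.9), a difference of -2.32 points, while the mean of single cytosines was 18.8% and 19.0%, a difference of 0.160 points. In inoculated plants the read-weighted CG level was 17.1% in Col-0, 16.6% in METS1#1 and 16.1% in METS1#2, differences of -0.497 and -1.04 points, and the means of single cytosines differed by 0.306 and 0.395 points. Read-weighted CHG levels were 7.25%, 6.81%, 7.02%, 6.82% and 6.49% in Col-0 mock, Col-0 Pst, METS1#1 mock, METS1#1 Pst and METS1#2 Pst. The CHH level by reads was 4.20% in Col-0 mock and 4.09% in METS1#1 mock, against 3.61% and 4.20% by the mean of single cytosines. In inoculated plants CHH was higher in both METS1 lines by either measure, by 0.391 points in METS1#1 and 0.797 points in METS1#2 over reads and by 0.255 and 0.209 points over single cytosines. Wilson intervals cover only the counting error of independent calls. Calls at several cytosines of the same read are not independent, so the intervals may be too narrow.

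**Figure D3:**
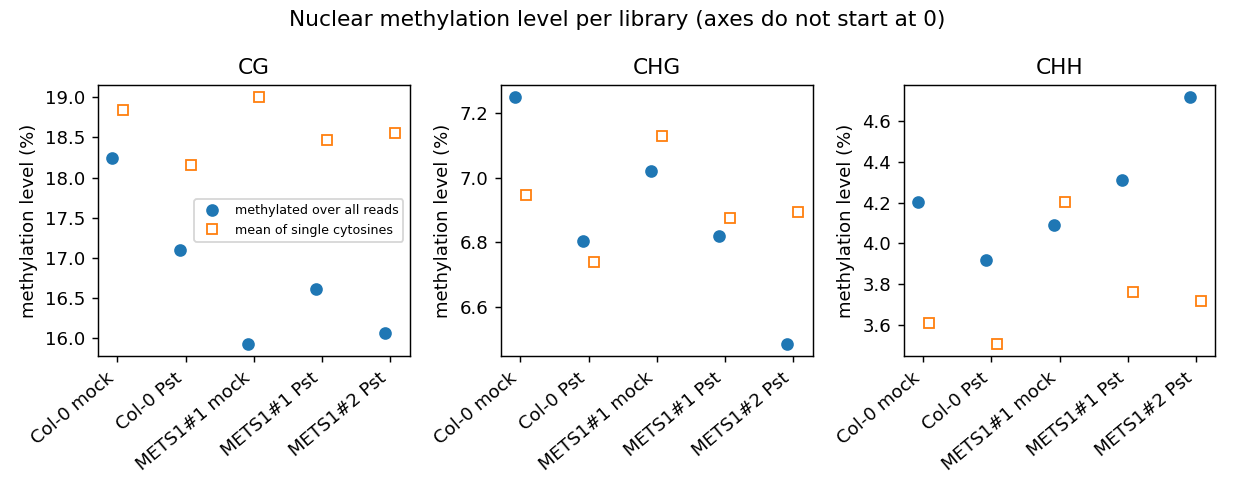
Methylation level (vertical axis, percent) over nuclear cytosines with at least 5 reads in all 5 libraries, in CG, CHG and CHH; filled circles are methylated over all reads and open squares the mean of single cytosines, and the axes do not start at 0. CG by reads runs from 15.9% in METS1#1 mock to 18.2% in Col-0 mock, while the mean of single cytosines lies between 18.2% and 19.0%.

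The reads were concentrated at few places. Cytosines covered by more than 100 reads in any library made up 1.13% of the CG cytosines and held 37.1% to 40.2% of the CG calls. Their CG level was 16.0% in Col-0 mock, 14.7% in Col-0 Pst, 11.4% in METS1#1 mock, 12.8% in METS1#1 Pst and 11.5% in METS1#2 Pst. Those on chromosome 2 from 1 to 100000, where a ribosomal RNA gene array lies, held 12.3% of the set's CG calls, with CG levels of 14.99%, 13.7%, 11.5%, 12.004% and 9.98% in the same order. Those on chromosome 3 from 14100001 to 14200000 held 13.7%, with levels of 10.7%, 9.97%, 8.15%, 8.71% and 7.73%. Without cytosines over 100 reads, a setting added after the data were seen, the METS1#1 mock CG difference was -0.635 points and those of METS1#1 Pst and METS1#2 Pst were 0.399 and 0.128 points.

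In METS1#1 mock the averaging also set the sign of CG in the other region classes, and that of CHH in promoters and arms. The read-weighted CG difference of METS1#1 mock from Col-0 mock was -1.29 points in gene bodies, -1.24 points in promoters, -4.11 points in pericentromeres and -1.19 points in chromosome arms, against 0.126, 0.0726, 0.346 and 0.118 points for the mean of single cytosines. For CHH the same comparison gave 0.0104 points in gene bodies, -0.108 points in promoters, 0.0275 points in pericentromeres and -0.00372 points in arms over reads, against 0.406, 0.584, 1.10 and 0.423 points over single cytosines. In METS1#1 Pst, CHH was above Col-0 Pst by 0.312 points in gene bodies, 0.450 points in promoters, 0.505 points in pericentromeres and 0.375 points in arms. In METS1#2 Pst the same differences were 0.796, 1.18, 0.642 and 1.02 points. Over single cytosines these 8 differences lay between 0.0839 and 0.696 points. Read-weighted CG differences from Col-0 Pst, in the same order of regions, were -0.0427, -0.524, -0.985 and -0.168 points in METS1#1 Pst. In METS1#2 Pst they were -0.211, -1.18, -1.51 and -0.515 points. Over single cytosines CG gave 0.174, 0.0776, 1.10 and 0.126 points in METS1#1 Pst and 0.253, 0.116, 1.28 and 0.195 points in METS1#2 Pst.

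In mock-treated plants, windows of 200 bp that differed between METS1#1 and Col-0 were mostly CHH windows with more methylation in METS1#1. Fisher's exact test on the reads, with Benjamini-Hochberg adjustment, called 630 of 309044 CHH windows higher and 96 lower, 51 and 50 of 153613 CG windows, and 2 and 1 of 185147 CHG windows. At equal coverage 510 CHH windows were higher and 36 lower, and 21 and 29 CG windows. By adjusted p alone, without the smallest difference, 184 CG windows were higher and 226 lower, and 4 and 26 CHG windows. Libraries drawn without a difference gave 0 called windows in each context and comparison, which covers independent counting error only. Among protein-coding genes, 153 had a promoter or gene body with higher CHH and 55 with lower CHH, and 135 and 6 with the coverage of both libraries made equal at each cytosine. The largest CHH rises were at AT5G27440 (body, 65.5% against 28.4%), AT1G68670 (promoter, 37.8% against 3.04%), the mevalonate kinase gene MK (AT5G27450, promoter, 55.6% against 21.3%, overlapping AT5G27440) and ASE1 (AT2G16570, promoter, 58.3% against 27.6%), which encodes an enzyme of purine synthesis. The largest CHH falls, by 24.8, 21.0, 20.8 and 20.4 points, were at the promoters of AT3G17740, AT5G45360, EPF2 (AT1G34245), which encodes a secreted peptide that limits stomatal lineage divisions, and AT5G18460. At equal coverage, all 4 rises stayed past the thresholds and none of the 4 falls did. AT3G17740 kept its size (-20.8 points) without passing the adjusted p, while AT5G45360 ended at -3.32, EPF2 at -0.422 and AT5G18460 at 4.13 points. In CG, the body of AT2G38590 was lower (17.2% against 58.5%), and in CHG the promoters of AT1G54680 (56.3% against 30.8%) and AT4G05340 (30.0% against 6.73%) were higher, but at equal coverage these 3 no longer passed the thresholds, with differences of -38.9, 11.1 and 8.43 points.

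In inoculated plants, METS1#1 had 317 CHH windows higher and 87 lower than Col-0 of 284182 tested, 26 and 22 CG windows of 122716, and 2 and 0 CHG windows of 152288. By adjusted p alone the counts were 68 and 85 in CG. Equal coverage gave 194 and 53 CHH windows and 3 and 12 CG windows. CHH was higher at 144 protein-coding genes and lower at 29, and at 71 and 10 at equal coverage. The 4 largest rises were at the promoters of XTH28 (AT1G14720, 67.4% against 34.1%), which encodes a cell wall enzyme, the MADS-box gene GOA (AT1G31140, 33.0% against 3.88%) and the DNA repair gene MRE11 (AT5G54260, 45.9% against 19.3%), and in the body of AT5G03710 (31.4% against 6.16%). The 4 largest falls were at ETC2 (AT2G30420, promoter, 17.4% against 40.8%), a regulator of trichome patterning, TADA (AT1G68720, promoter, 22.4% against 44.8%), QWRF2 (AT1G49890, promoter, 17.9% against 38.8%) and AT4G18720 (body, 26.0% against 45.5%). At equal coverage XTH28, GOA, AT5G03710 and ETC2 kept their calls, whereas MRE11 stood at 7.44 points, TADA at -7.62, QWRF2 at -2.71 and AT4G18720 at -2.75 points.

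METS1#2 inoculated with Pst had 458 CHH windows higher and 153 lower than Col-0 Pst of 212134 tested, 21 and 11 CG windows of 79761, and 5 and 0 CHG windows of 98674. The balance turned with the adjusted p alone, by which 38 CG windows were higher and 106 lower, and 5 and 39 CHG windows. Equal coverage gave 311 and 117 CHH windows, 5 and 5 CG windows and 1 CHG window. CHH was higher at 367 protein-coding genes and lower at 67, in the library with the lowest depth, and these counts became 151 and 55 at equal coverage. The 4 largest CHH rises were at GOA (promoter, 57.4% against 8.33%), AT5G19800 (body, 36.8% against 1.79%), HL (AT5G54390, promoter, 43.6% against 17.5%) and AT3G51325 (body, 46.9% against 20.8%). The 4 largest falls were at RTFL10 (AT3G14362, promoter, 30.7% against 62.6%), AT3G43110 (body, 44.3% against 74.1%), AT4G13210 (promoter, 46.1% against 75%) and the brassinosteroid synthesis gene CPD (AT5G05690, promoter, 28.0% against 55.2%). Of these 8, AT4G13210 lost its call at equal coverage (-12 points). CHG was higher in the bodies of AT1G13470 (55.7% against 24.0%), AT3G22770 (33.6% against 9.77%) and the nitrate transporter gene NRT1.5 (AT1G32450, 23.5% against 2.65%), none of which passed the thresholds at equal coverage, although their differences stayed at 30.1, 21.9 and 19.9 points.

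Windows called in both METS1 lines against Col-0 Pst numbered 113 higher and 23 lower in CHH, 2 higher and 1 lower in CG and 1 higher in CHG. Independent lists of the same lengths would share 0.702 and 0.0593 CHH windows, but these lists are not independent: both comparisons use 1 control library that cannot be split, so how much of the CHH sharing comes from that library is unknown. At equal coverage 73 CHH windows were called higher and 17 lower in both lines, and 0 CG and 0 CHG windows, so the CG and CHG windows named next did not pass in both lines there. The CHG window on chromosome 1 from 11716201 to 11716400, in NRT1.5, was at 43.0% in METS1#1 Pst, 55.6% in METS1#2 Pst and 1.35% and 1.61% in Col-0 Pst at the cytosines of each comparison. The adjoining CHG window, from 11716001 to 11716200, was called in METS1#1 mock against Col-0 mock (41.0% against 8.38%). A CG window on chromosome 2 from 10263001 to 10263200, in AT2G24140, was at 88.5% and 81.8% against 29.4% and 26.2%, and was also called in METS1#1 mock against the separate Col-0 mock library (87.7% against 19.5%). The CG window lower in both lines lay on chromosome 2 from 6831401 to 6831600, in AT2G15680 and AT2G15690, at 22.7% and 34.8% against 83.3%, and was called in mock plants as well (27.0% against 72.9%). By contrast, the other CG window higher in both lines, on chromosome 2 from 6508401 to 6508600 with no annotated gene, was at 71.2% and 82.4% against 16.7% in Col-0 Pst, and Col-0 Pst was also called lower there than Col-0 mock (80.2%). In CHH, a window on chromosome 3 from 22726601 to 22726800, in the promoter region of AT3G61415, was at 60.9% and 54.3% against 10.9%, and one on chromosome 3 from 9456201 to 9456400, in the body of AT3G25840, was at 27.8% and 21.5% against 69.1% and 67.3%.

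Infection was compared within each genotype. In Col-0, 172 CHH windows were higher and 173 lower after Pst of 338508 tested, 0 and 8 CG windows of 157031 and 0 CHG windows of 194885, where 867 and 1495 had an unadjusted p under 0.05, and CHH counts at equal coverage were 106 and 102. Higher CHH was called at 52 protein-coding genes and lower CHH at 45 (16 and 16 at equal coverage), led by AT1G77855 (body, 60.6% against 36.1%) and AT3G43110 (body, 43.6% against 19.4%) upward and by XTH28 (promoter, 18.2% against 44.5%) and AT2G04480 (promoter, 10.4% against 34.5%) downward. None of these 4 kept its call at equal coverage, where their differences were 0.319, 7.74, -16.7 and -13.5 points. In METS1#1, 222 CHH windows were higher and 422 lower of 265500, 0 and 3 CG windows of 123426 and 0 CHG windows of 148638, where 1228 and 1323 had an unadjusted p under 0.05, and CHH counts at equal coverage were 94 and 346. Higher CHH was called at 145 genes and lower CHH at 138, and at 31 and 109 at equal coverage. AIG2 (AT3G28930, body, 63.0% against 34.8%) and AT1G70470 (body, 39.8% against 13.1%) led upward, and AT5G27440 (body, 23.7% against 61.6%) and MK (promoter, 19.3% against 53.1%) downward. The METS1#1 mock library thus stood apart at AT5G27440 and MK in both comparisons that use it. Likewise, Col-0 Pst was the lower library at XTH28 against both METS1#1 Pst and Col-0 mock. It was the higher one at AT3G43110 against both METS1#2 Pst and Col-0 mock. AIG2, a gene induced during bacterial infection, stood at 0.446 points at equal coverage, while AT1G70470, AT5G27440 and MK kept their calls. The MADS-box gene AGL85 (AT1G54760) was higher in CHG in its body (56.1% against 25.9%) and lost its call at equal coverage (17.6 points). The read-weighted change in CG level with Pst was -1.15 points in Col-0 and 0.678 points in METS1#1, a second-order difference of 1.82 points with no test. The changes in the mean of single cytosines were -0.684 and -0.539 points.

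**Figure D4:**
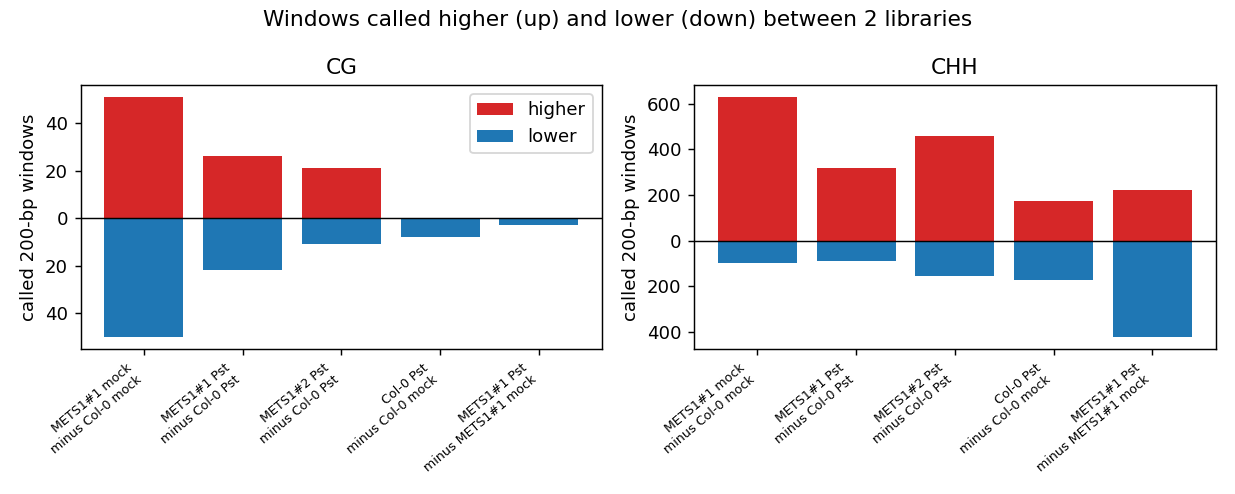
Number of 200-bp windows called higher (bars above 0) and lower (bars below 0) in the first library than in the second (vertical axis, count), for the 5 comparisons in CG and CHH. In CHH, METS1#1 mock had 630 windows above and 96 below Col-0 mock, and the 2 Col-0 libraries differed at 172 and 173 windows.

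Called CHH windows differed in CG level and in how their methylation was spread over the strands. Of 2730 CHH calls summed over the 5 comparisons, where a window called in several counts each time, 42.0% had a CG level below 20%, 28.5% had 20% or more and 29.5% had no covered CG cytosine, where the shares of tested windows were 53.5%, 26.2% and 20.3%. In the 937 windows of the first class that were covered on both strands, the strand with more methylation had a median CHH level of 26.5% and the other strand 0.495%, with a median of 19 and 4 covered cytosines. Both strands moved in the direction of the call in 30.4% of these windows and in 56.3% of the 549 windows covered on both strands with CG at 20% or more. The latter had median strand levels of 37.7% and 6.39%. The 348 windows covered on both strands with no covered CG cytosine were like the first class. Their median strand levels were 30.1% and 0.326%, and both strands moved in 25.9% of them. A strand without any difference does not count as moved, so levels near 0 on few cytosines lower the shares of 30.4% and 25.9%. The CHH genes named above resembled the first class, with CG levels under 5% in the called region and CHH levels under 5% on the other strand wherever these were covered, except for CG at AT3G17740 (17.9% and 30.6%), TADA (31.3% and 25%) and AT2G04480 (0% and 6.25%). Most gene regions called higher in CHH also had a CG level below 20%, where CG was covered. These were 112 of 135 promoters and 44 of 60 bodies in METS1#1 mock against Col-0 mock. Against Col-0 Pst they were 111 of 126 and 47 of 54 in METS1#1 Pst, and 292 of 310 and 134 of 153 in METS1#2 Pst. The share among all tested gene regions was not counted.

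Few members of the 9 gene lists fixed before the data were examined had a called promoter or body, and all such calls were in CHH. Calls were rare among all protein-coding genes too. In CHH, 153 were higher and 55 lower of 26233 tested in METS1#1 mock, and 367 and 67 of 25033 in METS1#2 Pst, each against Col-0. Whether list members were called more or less often than other genes was not tested. Of 19 one-carbon and methionine cycle genes, only SAHH2 (AT3G23810, promoter, chromosome 3 from 8588714 to 8589740), which encodes S-adenosylhomocysteine hydrolase, was called, with 21.3% in METS1#1 mock against 10.1% in Col-0 mock, and at equal coverage the difference was -0.739 points. Of 20 genes of the DNA methylation machinery, the promoter of the CG methyltransferase gene MET1 (AT5G49160, chromosome 5 from 19932144 to 19933201) was at 44.2% in METS1#1 mock against 33.5% in Col-0 mock, and at 30.2% in METS1#1 Pst against 42.2% in METS1#1 mock. These differences were 7.92 and -6.05 points at equal coverage, under the threshold, and 18.02 and -19.8 points with at least 10 reads. The promoter of VIM1 (AT1G57820, chromosome 1 from 21416947 to 21417977), a cofactor of CG maintenance, was at 40.7% in METS1#1 Pst against 23.1% in Col-0 Pst and 39.6% against 13.9% in METS1#1 mock, and kept both calls at equal coverage, with differences of 13.2 and 13.4 points, against 25.7 points before in the latter. Both comparisons use the METS1#1 Pst library. The promoter of SUVH5 (AT2G35160), a histone methyltransferase gene, was at 16.8% in METS1#2 Pst against 1.32% in Col-0 Pst, with CG levels of 26.9% and 35.4%, and stood at 9.497 points at equal coverage. Among 9 loci known to be controlled by methylation, EPF2 was lower in METS1#1 mock as given above, the floral gene SUP (AT3G23130, promoter) was lower in METS1#2 Pst (16.4% against 33.0%, and -25 points at equal coverage) and AG (AT4G18960, body) was higher there (20.9% against 9.90%, 0.397 points at equal coverage). CG levels were under 5% in the called regions of SAHH2, MET1, VIM1, SUP and AG, and so was CHH on their other strand. With both libraries pooled, the strands of VIM1 stood at 42.5% and 1.19% CHH in METS1#1 Pst against Col-0 Pst. Those of SUVH5 stood at 12.1% and 1.18%. The other strand of MET1 rested on 1 cytosine. These list calls thus lay mostly on 1 strand. No member of the lists for salicylic acid defence (18 genes), pattern-triggered immunity (13), NLR immune receptors (13), jasmonate defence (8), DNA demethylation (6) and housekeeping (6) was called in any of the 5 comparisons.

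Median differences of the lists lay mostly inside the range of 10000 random lists of like size, level and coverage. Of 90 percentiles, 3 fell outside the central 95%, where 4.5 would by chance, and they describe these libraries only. The loci known to be controlled by methylation were lower in Col-0 Pst than in Col-0 mock in promoters (median -1.82 points, percentile 0.190, 8 genes) and in gene-body CG (median -1.08 points, percentile 2.10, 7 genes), but the promoter percentile was 16.2 with at least 10 reads and 71.5 with cytosines outside the gene. NLR receptor promoters were higher in METS1#2 Pst (median 0.484 points, percentile 97.9, 12 genes), and the percentile was 58.5 with at least 10 reads (4 genes) and 98.2 with cytosines outside the gene. In METS1#1 mock the promoter percentiles were 55.6 for the one-carbon list, 14.6 for the methylation machinery, 5.32 for salicylic acid defence and 35.9 for pattern-triggered immunity.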

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

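All tests of explanations in this part were chosen after the results were seen, and their bounds were set then.

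The read-weighted levels moved in opposite directions with Pst in METS1#1 and Col-0, with second-order differences of 1.82 points in CG and 0.502 points in CHH that were not tested. Without cytosines over 100 reads the METS1#1 change was 0.0236 points in CG, within counting error of 0, so a few heavily read loci may account for the CG rise, though the gap to Col-0 was still 1.03 points. In CHH it was 0.0766 points, above the counting error of independent calls, and the spread between libraries that would judge it is not known. Coverage that differs from cytosine to cytosine may account for the opposite signs: at equal coverage the changes in CG and CHH were -0.415 and -0.487 points in METS1#1 and -0.792 and -0.125 points in Col-0. Whether METS1#1 responds in another way than Col-0 remains open, with values of 0.145 points in CG and -0.337 points in CHH for the mean of single cytosines, the latter of opposite sign to the read-weighted value, and no replicates to judge them against.

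Transposon CHH was higher in the 3 METS1 libraries than in Col-0 given the same treatment, by 1.04, 0.978 and 0.809 points. Incomplete conversion spread evenly over all DNA is argued against, since plastid CHH differed by only 0.0827 points for METS1#1 mock and by -0.0397 and -0.0533 points for the inoculated lines. Plastid DNA cannot show incomplete conversion limited to parts of the nuclear DNA, so that remains open. Over single cytosines, CHH in METS1#1 mock was 1.10 times that of Col-0 mock in transposons. In protein-coding genes with levels under 5% in all contexts it was 1.17 times. After Pst these ratios to Col-0 were 1.09 and 0.971 in METS1#1 and 1.09 and 0.986 in METS1#2. Unequal depth is argued against too, because the smallest of the 3 differences at equal coverage was 0.834 points. An effect of METS1 overexpression may underlie the difference but remains untested: the 2 Col-0 libraries differed by -0.890 points, 1 library stands for each group, and the inoculated METS1 libraries alone had 2 sequencing runs.

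CHH windows called where CG methylation is low made up 42.0% of the calls summed over the 5 comparisons and 53.5% of the windows tested. Unconverted or misplaced reads of 1 strand may explain them, as, in windows covered on both strands, the median level on the less methylated strand was 0.495%, against 6.39% in windows with CG at 20% or more; which of these it was, and whether single-stranded methylation occurs there, was not tested. A lasting difference of line METS1#1 is argued against for most of these windows, as 51.6% of 248 called in the mock comparison differed in the same direction after Pst (exact 95% interval 45.2 to 58.0). Windows with no covered CG cytosine, 29.5% of the calls, had a like split between strands, with medians of 30.1% and 0.326%. The question of reads of 1 strand thus stands for them too.

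The mitochondrial genome, which no comparison used, had CG levels of 8.20%, 7.43%, 8.11%, 8.15% and 7.27%, CHG levels of 4.89%, 4.48%, 4.95%, 4.83% and 4.45% and CHH levels of 1.82%, 1.70%, 2.05%, 1.86% and 1.71% in Col-0 mock, Col-0 Pst, METS1#1 mock, METS1#1 Pst and METS1#2 Pst, with METS1#1 above Col-0 beyond counting error in all contexts after Pst and in mock for CHH only. METS1#2 Pst was not above Col-0 Pst beyond counting error in any context. Counting error here is that of independent calls, and no replicate shows how far like libraries vary. Whether all reads placed on this genome came from mitochondrial DNA was not tested.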

How the results depend on the processing

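The settings added after the data were seen were removal of cytosines over 100 reads, the mean of single cytosines for region classes, promoter cytosines outside the gene, the CG requirement for CHH windows, METS1 coverage and CG level over cytosines listed in all libraries, and all alternatives for gene counts and the infection response. Each list of 5 values is in the order METS1#1 mock minus Col-0 mock, METS1#1 Pst minus Col-0 Pst, METS1#2 Pst minus Col-0 Pst, Col-0 Pst minus mock and METS1#1 Pst minus mock, and levels are in percentage points. Thinning to equal coverage used 1 random seed, and among 47 named calls it left 21 past the thresholds, ended 24 and reversed 2. Promoters extending further upstream were not run. Leaving out a library, other splits of the samples and paired tests were not done, as each group has 1 library. With at least 10 reads, 30 named regions had too few cytosines for a value. The cause of these shifts was not tested here.

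CG level differences with at least 10 reads were -4.18, -1.53, -2.39, -1.37 and 1.29. Equal coverage gave -0.614, -0.285, -0.816, -0.792 and -0.415 for CG. CG cytosines of the compared pair alone gave -1.57, -0.0596, -0.707, -1.10 and 0.541. Means of single CG cytosines gave 0.160, 0.306, 0.395, -0.684 and -0.539. Removing CG cytosines over 100 reads gave -0.635, 0.399, 0.128, -1.01 and 0.0236. Plastid correction of CG gave -2.31, -0.448, -1.02, -1.17 and 0.691. For CG the METS1#1 change with Pst minus that of Col-0 was 2.65 (at least 10 reads), 0.377 (equal coverage), 0.145 (the mean of single cytosines), 1.64 (cytosines of the compared pair), 1.03 (cytosines over 100 reads removed) and 1.86 (plastid correction).

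CHG level differences with at least 10 reads were -1.16, -0.362, -0.712, -0.485 and 0.314. Equal coverage gave 0.0734, 0.0227, -0.113, -0.242 and -0.275 for CHG. CHG cytosines of the compared pair alone gave 0.0336, 0.110, -0.255, -0.380 and -0.282. Means of single CHG cytosines gave 0.185, 0.136, 0.154, -0.206 and -0.254. Removing CHG cytosines over 100 reads gave 0.312, 0.219, -0.0971, -0.443 and -0.536. Plastid correction of CHG gave -0.176, 0.0880, -0.262, -0.458 and -0.195. For CHG the METS1#1 change with Pst minus that of Col-0 was 0.799 (at least 10 reads), -0.0325 (equal coverage), -0.0481 (the mean of single cytosines), 0.0974 (cytosines of the compared pair), -0.0925 (cytosines over 100 reads removed) and 0.264 (plastid correction).

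CHH level differences with at least 10 reads were -0.578, 0.490, 1.23, -0.335 and 0.734. Equal coverage gave 0.635, 0.331, 0.313, -0.125 and -0.487 for CHH. CHH cytosines of the compared pair alone gave 0.163, 0.303, 0.680, -0.223 and -0.0530. Means of single CHH cytosines gave 0.592, 0.255, 0.209, -0.101 and -0.438. Removing CHH cytosines over 100 reads gave 0.214, 0.541, 1.03, -0.250 and 0.0766. Plastid correction of CHH gave -0.192, 0.434, 0.856, -0.299 and 0.327. For CHH the METS1#1 change with Pst minus that of Col-0 was 1.07 (at least 10 reads), -0.362 (equal coverage), -0.337 (the mean of single cytosines), 0.170 (cytosines of the compared pair), 0.327 (cytosines over 100 reads removed) and 0.626 (plastid correction).

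In transposons, CG differences were 2.24, 1.47, 0.839, -3.03 and -3.81 with at least 10 reads. CG in transposons gave 0.445, 1.58, 1.89, -3.72 and -2.54 at equal coverage. Means of CG cytosines in transposons gave 0.441, 1.65, 2.01, -3.81 and -2.60. In transposons, CHG differences were 1.71, 1.61, 0.950, -1.51 and -1.61 with at least 10 reads. CHG in transposons gave 1.202, 1.25, 1.32, -1.55 and -1.51 at equal coverage. Means of CHG cytosines in transposons gave 1.197, 1.198, 1.35, -1.56 and -1.55. In transposons, CHH differences were 0.884, 0.850, 0.866, -0.902 and -0.936 with at least 10 reads. CHH in transposons gave 0.995, 0.888, 0.834, -0.790 and -0.916 at equal coverage. Means of CHH cytosines in transposons gave 1.04, 0.903, 0.840, -0.769 and -0.908.

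In gene bodies, CG differences were -2.47, -0.844, -1.49, -0.945 and 0.684 with at least 10 reads. CG in gene bodies gave -0.254, -0.0704, -0.217, -0.499 and -0.268 at equal coverage. Means of CG cytosines in gene bodies gave 0.126, 0.174, 0.253, -0.376 and -0.328. In gene bodies, CHG differences were -0.826, -0.327, -0.661, -0.310 and 0.190 with at least 10 reads. CHG in gene bodies gave 0.00269, -0.0411, -0.0903, -0.0981 and -0.134 at equal coverage. Means of CHG cytosines in gene bodies gave 0.0525, -0.00309, 0.0103, -0.0550 and -0.111. In gene bodies, CHH differences were -0.337, 0.781, 1.95, -0.110 and 1.01 with at least 10 reads. CHH in gene bodies gave 0.479, 0.204, 0.232, 0.000691 and -0.327 at equal coverage. Means of CHH cytosines in gene bodies gave 0.406, 0.101, 0.0839, 0.00837 and -0.296.

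In promoters, CG differences were -2.67, -1.44, -2.71, -0.902 and 0.331 with at least 10 reads. CG in promoters gave -0.796, -0.541, -1.09, -0.530 and -0.217 at equal coverage. Means of CG cytosines in promoters gave 0.0726, 0.0776, 0.116, -0.235 and -0.230. In promoters, CHG differences were -0.888, -0.383, -0.877, -0.292 and 0.213 with at least 10 reads. CHG in promoters gave -0.0496, -0.0940, -0.281, -0.138 and -0.164 at equal coverage. Means of CHG cytosines in promoters gave 0.0733, 0.00509, 0.0159, -0.0584 and -0.127. In promoters, CHH differences were -0.390, 0.631, 1.77, -0.120 and 0.902 with at least 10 reads. CHH in promoters gave 0.565, 0.262, 0.277, -0.0105 and -0.389 at equal coverage. Means of CHH cytosines in promoters gave 0.584, 0.208, 0.159, 0.00390 and -0.373.

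In pericentromeres, CG differences were -5.17, -1.81, -2.33, -1.62 and 1.75 with at least 10 reads. CG in pericentromeres gave -0.981, -0.387, -1.25, -1.32 and -0.680 at equal coverage. Means of CG cytosines in pericentromeres gave 0.346, 1.10, 1.28, -2.51 and -1.75. In pericentromeres, CHG differences were -1.47, -0.364, -0.537, -0.620 and 0.486 with at least 10 reads. CHG in pericentromeres gave 0.236, 0.255, -0.0433, -0.596 and -0.583 at equal coverage. Means of CHG cytosines in pericentromeres gave 0.832, 0.900, 0.874, -1.02 and -0.954. In pericentromeres, CHH differences were -0.550, 0.295, 0.563, -0.460 and 0.385 with at least 10 reads. CHH in pericentromeres gave 0.847, 0.505, 0.422, -0.323 and -0.720 at equal coverage. Means of CHH cytosines in pericentromeres gave 1.10, 0.696, 0.575, -0.487 and -0.895.

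In chromosome arms, CG differences were -2.50, -1.04, -2.30, -0.950 and 0.508 with at least 10 reads. CG in chromosome arms gave -0.391, -0.222, -0.535, -0.447 and -0.249 at equal coverage. Means of CG cytosines in chromosome arms gave 0.118, 0.126, 0.195, -0.271 and -0.263. In chromosome arms, CHG differences were -0.645, -0.288, -0.732, -0.289 and 0.0678 with at least 10 reads. CHG in chromosome arms gave -0.0158, -0.0948, -0.157, -0.0644 and -0.126 at equal coverage. Means of CHG cytosines in chromosome arms gave 0.0284, -0.0477, -0.0201, -0.00866 and -0.0848. In chromosome arms, CHH differences were -0.484, 0.865, 2.36, -0.0735 and 1.28 with at least 10 reads. CHH in chromosome arms gave 0.487, 0.201, 0.244, 0.0274 and -0.325 at equal coverage. Means of CHH cytosines in chromosome arms gave 0.423, 0.109, 0.0886, 0.0261 and -0.288.

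CG windows higher with at least 10 reads made up 0.0575, 0.0325, 0.0139, 0 and 0% of those tested. At equal coverage, CG windows higher made up 0.0137, 0.00244, 0.00627, 0 and 0% of those tested. CG windows of 500 bp higher made up 0.0282, 0.0106, 0.0163, 0 and 0% of those tested. CG windows holding 6 cytosines and higher made up 0.0151, 0.0148, 0.0151, 0 and 0% of those tested. Lower thresholds called CG windows higher that made up 0.0970, 0.0489, 0.0401, 0.000637 and 0.00243% of those tested. Single CG cytosines higher made up 0.0220, 0.00364, 0.00314, 0 and 0% of those tested. CG windows lower with at least 10 reads made up 0.0447, 0.0232, 0.0278, 0.00308 and 0% of those tested. At equal coverage, CG windows lower made up 0.0189, 0.00978, 0.00627, 0.00255 and 0.000810% of those tested. CG windows of 500 bp lower made up 0.0174, 0.00772, 0.00814, 0.00559 and 0.00491% of those tested. CG windows holding 6 cytosines and lower made up 0.0121, 0.0148, 0.0113, 0.00467 and 0% of those tested. Lower thresholds called CG windows lower that made up 0.0788, 0.0285, 0.0226, 0.0108 and 0.0138% of those tested. Single CG cytosines lower made up 0.0185, 0.00278, 0.00215, 0 and 0% of those tested.

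CHG windows higher with at least 10 reads made up 0.00583, 0.00922, 0.0154, 0 and 0% of those tested. At equal coverage, CHG windows higher made up 0.000540, 0.000657, 0.00101, 0 and 0% of those tested. CHG windows of 500 bp higher made up 0.00528, 0.000843, 0.00682, 0 and 0.00174% of those tested. CHG windows holding 6 cytosines and higher made up 0.00378, 0.00538, 0.0144, 0 and 0% of those tested. Lower thresholds called CHG windows higher that made up 0.00108, 0.00131, 0.00507, 0 and 0% of those tested. Single CHG cytosines higher made up 0, 0, 0, 0 and 0% of those tested. CHG windows lower with at least 10 reads made up 0.00194, 0, 0.0154, 0 and 0% of those tested. At equal coverage, CHG windows lower made up 0.000540, 0, 0, 0 and 0% of those tested. CHG windows of 500 bp lower made up 0.00226, 0, 0, 0 and 0.000869% of those tested. CHG windows holding 6 cytosines and lower made up 0.00378, 0.00179, 0.00359, 0 and 0% of those tested. Lower thresholds called CHG windows lower that made up 0.000540, 0, 0, 0 and 0% of those tested. Single CHG cytosines lower made up 0, 0, 0, 0 and 0% of those tested.

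CHH windows higher with at least 10 reads made up 0.302, 0.315, 1.29, 0.0825 and 0.140% of those tested. At equal coverage, CHH windows higher made up 0.165, 0.0683, 0.147, 0.0313 and 0.0354% of those tested. CHH windows of 500 bp higher made up 0.305, 0.186, 0.334, 0.0805 and 0.148% of those tested. CHH windows holding 6 cytosines and higher made up 0.279, 0.167, 0.366, 0.0715 and 0.124% of those tested. Lower thresholds called CHH windows higher that made up 0.224, 0.133, 0.267, 0.0638 and 0.0991% of those tested. Single CHH cytosines higher made up 0.00276, 0, 0, 0 and 0% of those tested. CHH windows higher with CG at 20% or more made up 0.293, 0.107, 0.154, 0.0363 and 0.0557% of those tested. CHH windows lower with at least 10 reads made up 0.0305, 0.0678, 0.378, 0.0609 and 0.311% of those tested. At equal coverage, CHH windows lower made up 0.0116, 0.0186, 0.0552, 0.0301 and 0.130% of those tested. CHH windows of 500 bp lower made up 0.0607, 0.0450, 0.0881, 0.0810 and 0.229% of those tested. CHH windows holding 6 cytosines and lower made up 0.0428, 0.0488, 0.123, 0.0715 and 0.234% of those tested. Lower thresholds called CHH windows lower that made up 0.0421, 0.0341, 0.0750, 0.0567 and 0.172% of those tested. Single CHH cytosines lower made up 0, 0, 0, 0 and 0.000775% of those tested. CHH windows lower with CG at 20% or more made up 0.0324, 0.0331, 0.0620, 0.0669 and 0.219% of those tested.

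Protein-coding genes with higher CHH numbered 135, 71, 151, 16 and 31 at equal coverage and 145, 147, 266, 49 and 97 with at least 10 reads. Protein-coding genes with lower CHH numbered 6, 10, 55, 16 and 109 at equal coverage and 33, 21, 56, 36 and 109 with at least 10 reads. CG windows called in both lines numbered 1 higher and 1 lower with at least 10 reads, and 0 and 0 at equal coverage. CHG windows called in both lines numbered 0 higher and 0 lower with at least 10 reads, and 0 and 0 at equal coverage. CHH windows called in both lines numbered 80 higher and 20 lower with at least 10 reads, and 73 and 17 at equal coverage. The coverage ratios of the METS1 body over cytosines listed in all libraries were 1.66, 1.95 and 1.91 in the 3 METS1 libraries, and its CG levels there were 18.2, 21.5, 13.3, 13.8 and 11.8% in Col-0 mock, Col-0 Pst, METS1#1 mock, METS1#1 Pst and METS1#2 Pst. The SAHH2 promoter difference was -0.198 points with at least 10 reads and -0.739 at equal coverage, and that of AT5G18460 was 4.13 at equal coverage.

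List percentiles that crossed the bounds of the central 95% were 1.10 for pattern-triggered immunity promoters in METS1#1 Pst with cytosines outside the gene (16.0 before), 58.5 for NLR receptor promoters in METS1#2 Pst with at least 10 reads (97.9 before) and 16.2 for methylation-controlled loci promoters in Col-0 Pst minus mock with at least 10 reads (0.190 before). Others were 99 for housekeeping promoters in Col-0 Pst minus mock with at least 10 reads (67.4 before), 71.5 for methylation-controlled loci promoters in Col-0 Pst minus mock with cytosines outside the gene (0.190 before) and 0.100 for one-carbon promoters in METS1#1 Pst minus mock with at least 10 reads (23.3 before). The rest were 99.4 for methylation machinery promoters in METS1#1 Pst minus mock with at least 10 reads (91.5 before) and 99.0 for methylation-controlled loci promoters in METS1#1 Pst minus mock with cytosines outside the gene (80.6 before).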

Other observations

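The overlaps in this part between comparisons with no library in common, and the split of genes by level, were chosen after the data were seen.

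CG windows that differed between METS1#1 and Col-0 in mock plants tended to differ in the same direction after Pst, in libraries that were not shared. Of 34 windows called higher and tested in both comparisons, 30 were higher after Pst as well, and of 33 called lower, 33 were lower. Called in both were 1 and 8 windows, where independent lists would share 0.00706 and 0.00623. Of the CHH windows, 344 of 594 called higher and 28 of 92 called lower kept their sign, with 57 and 2 called in both, where independent lists would share 0.723 and 0.0311. Called in the opposite direction after Pst were 18 of those called higher and 12 of those called lower. For CHH windows called higher, the mean difference was 22.7 points in mock plants and 2.27 points after Pst. For those called lower it was -22.1 points and 4.22 points. The lower set thus did not repeat, and the higher set kept only a small part of its size.

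Protein-coding genes with levels under 5% in all contexts (4928 genes) had a CHH level, as the mean of single cytosines, of 1.03% in METS1#1 mock and 0.885% in Col-0 mock, and of 0.992% and 0.933% over reads. After Pst the mean of single cytosines was 0.883% in METS1#1 and 0.897% in METS1#2 against 0.909% in Col-0, while over reads it was 0.951% and 1.08% against 0.944%. METS1#2 Pst against Col-0 Pst and METS1#1 mock against Col-0 mock shared 45 CHH windows called higher, where independent lists would share 1.24. In METS1#2 Pst, 36 windows higher and 11 lower in METS1#1 mock were called in the opposite direction. Of 551 windows called higher in METS1#1 mock, 278 kept their sign in METS1#2 Pst, and of 83 called lower, 28 did. The mean difference of those called higher was 22.6 points in METS1#1 mock and 0.192 points in METS1#2 Pst, so their direction was not shared as a set. The Pst comparisons of Col-0 and METS1#1 shared 2 CHH windows called higher and 13 called lower, and 21 higher and 10 lower in Col-0 were called in the opposite direction in METS1#1.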
